A study of Mus musculus with 6 samples.

How the data were processed

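Ependymal cells were sorted by GFP from the ventricular-subventricular zone of adult mice 2 days after tamoxifen, per the labels, with 3 samples of the Ccn1 conditional knockout and 3 of the control. The genotype and replicate number of each sample were taken from its title. The submitters' processing notes name CASAVA 1.8, cutadapt 1.11, a trimmer of adapter sequence, and kallisto 0.42.5, which assigns reads to transcripts by pseudoalignment and shares ambiguous reads between them. The genome build, the annotation and the way in which transcripts were summed to genes are not given in the sources used here. The deposited files hold, per the file headers, an estimated count and a TPM value (abundance scaled for transcript length and library size) for each of 47643 genes. The estimated counts are not normalized and need not be whole, and they were rounded to whole numbers here. The deposited TPM values sum to the same total in each library. Since the files list genes, the planned test per transcript did not apply. Kallisto divides reads between near-identical copies by estimate, so genes of such families are uncertain.

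Gene identifiers were matched to GENCODE M21 on GRCm38 without their version number (99.1% matched), and coordinates are from that annotation. Older symbols in the files were translated through a fixed list. Genes were kept by filterByExpr, which left 11574 of the 19684 genes with a count in any library. Counts were scaled by TMM and tested with edgeR 4.0.16 by the quasi-likelihood test, with robust dispersion and the default method of that version, in R 4.3.3, with genotype as the only term. p-values were adjusted by Benjamini-Hochberg and called at 0.05. Levels are CPM, counts scaled to library size, after TMM scaling. Values measured once per library were compared by an exact two-sided permutation test over the 20 assignments of 3 samples to a group, which cannot give a p under 0.1. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 5 tested members, and again with an estimated correlation and with fry.

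The design, the settings to be compared, 43 gene lists and the rule for named genes were fixed before the data were examined. The rule took Ccn1 first, then genes past the adjusted threshold with separate groups and a mean of at least 5 CPM, filled up to 24 by smallest p where fewer passed, leaving out symbols that are only model numbers. From each list it took up to 2 members with the smallest p, and for identity and cell type lists the 3 most abundant. A part of these is given. The settings compared were DESeq2 1.42.0 with its Wald test, its size factors in edgeR, total counts only, other filters, limma-voom, limma on log2 TPM, the replicate number as a block, and each library left out in turn. Further filters and a newer edgeR quasi-likelihood method were added after the data had been seen. The tests were checked on counts simulated from these libraries with 200 genes changed by known folds. The libraries held 13401499 to 15689579 counts each. The common dispersion was 1.28, a coefficient of variation of 1.13 between libraries, and the median dispersion of single genes with a mean of at least 50 CPM was 0.123. Technical and biological spread are not separated in these values. Among genes with a mean of 100 to 200 counts, 70.7% had a library at 3 counts or fewer (32.8% at 200 to 400 counts), so the number of counts overstates the precision of such genes.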

Results

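RNA was sequenced from ependymal cells of the adult mouse ventricular-subventricular zone. Ependymal cells are the multiciliated cells that line the ventricle wall and border the neural stem cell niche. The mice had received tamoxifen 2 days earlier, which switched on a GFP marker in ependymal cells and, in the conditional knockout (cKO), deleted Ccn1, the gene of a secreted matricellular protein. GFP-positive cells were isolated by flow cytometry. There were 3 samples of the Ccn1 cKO and 3 of the control, 6 in all. The total of estimated counts per library ranged from 13401499 to 15689579. The totals of the 3 cKO and 3 control libraries overlapped (exact two-sided permutation p = 0.3, where 0.1 is the smallest value that 3 against 3 allows). Genes with at least 1 count numbered 14019 ± 448 in the cKO and 13278 ± 970 in the control (SD, n = 3 each, exact two-sided permutation p = 0.3). Mitochondrially encoded genes took 6.99 ± 0.50% of the counts in the cKO and 7.22 ± 1.03% in the control (exact permutation p = 0.9). Nuclear-retained RNAs took 0.68 ± 0.28% in the cKO and 0.41 ± 0.06% in the control (exact permutation p = 0.2).

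All 6 libraries carried a strong ependymal profile, and the 2 genotypes were alike in its summed level. Motile cilia genes, which build and drive the beating axoneme, summed to 20740 ± 428 CPM in the cKO and 21170 ± 1426 CPM in the control (SD, n = 3 each, exact two-sided permutation p = 0.9). Among the most abundant of them, Tmem212 stood at 2110 ± 48.8 against 2260 ± 425 CPM and Ccdc153 at 1610 ± 37.2 against 1803 ± 514 CPM. The list of other ependymal genes summed to 37149 ± 227 CPM in the cKO and 37930 ± 1385 CPM in the control (exact permutation p = 0.6). Its leading members were Nnat at 16838 ± 709 against 16955 ± 1741 CPM, Clu at 8875 ± 985 against 9363 ± 358 CPM and Rarres2, which encodes chemerin, at 3361 ± 85.6 against 3271 ± 599 CPM.

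Markers of other cells that the GFP gate could have held were mostly low, apart from the astrocyte and neural stem cell list. Microglial markers summed to 204 ± 15.5 CPM in the cKO and 216 ± 23.1 CPM in the control (SD, n = 3 each, exact permutation p = 0.6), and lymphocyte and granulocyte markers to 0.073 ± 0.073 and 0.13 ± 0.13 CPM (exact permutation p = 0.7). Oligodendrocyte markers summed to 871 ± 280 and 624 ± 319 CPM (exact permutation p = 0.4), and choroid plexus markers to 1707 ± 633 and 1520 ± 220 CPM (exact permutation p = 0.7). Endothelial markers summed to 1511 ± 115 and 1672 ± 89.1 CPM, most of it Pltp at 1416 ± 143 and 1586 ± 74.7 CPM. Mural and fibroblast markers summed to 656 ± 40.8 and 612 ± 177 CPM, most of it Acta2 at 498 ± 9.12 and 457 ± 153 CPM. Neuron markers summed to 520 ± 46.2 and 510 ± 147 CPM, most of it Ppp1r1b at 434 ± 72.3 and 455 ± 145 CPM. Enpp2, at 394 ± 293 and 170 ± 160 CPM, was on both the oligodendrocyte and the choroid plexus list. Markers of transit-amplifying cells and neuroblasts summed to 632 ± 125 CPM in the cKO and 892 ± 129 CPM in the control, with all 3 cKO libraries below all 3 controls (exact permutation p = 0.1, the smallest possible). Most of that sum was Cd24a, at 521 ± 129 and 740 ± 170 CPM, which was also on the ependymal list. Astrocyte and neural stem cell markers summed to 26996 ± 628 and 27288 ± 972 CPM (exact permutation p = 0.8), of which Apoe alone gave 20485 ± 1109 and 19934 ± 92.1 CPM. Whether ependymal cells or other sorted cells carried the transcripts of this list was not tested.

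**Figure D1:**
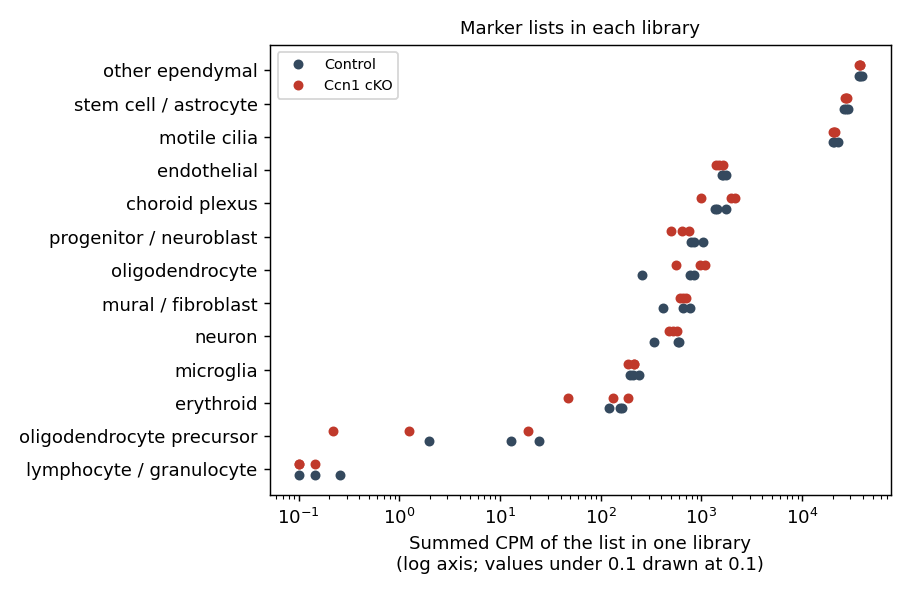
Summed CPM (counts scaled to library size) of 13 lists of cell markers in each of the 6 libraries, on a log axis, with control libraries in dark blue and Ccn1 cKO libraries in red. The 3 lists of ependymal and of stem cell or astrocyte genes lie at 20125 CPM or more in every library, and the other lists drawn lie at 2168 CPM or less. The lists of mitochondrially encoded, nuclear-retained and sex-linked genes are not drawn.

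The first comparison asked whether the deleted gene was lower in the cells labelled cKO. Ccn1 was 4.66-fold lower in the cKO, at 28.7 ± 10.4 CPM against 134 ± 20.6 CPM (SD, n = 3 each), which left 21.4% of the control level. The estimated counts were 411, 238 and 524 in the cKO libraries and 1665, 2037 and 2224 in the controls, so every library went with its label. In the deposited TPM values Ccn1 stood at 18.0 ± 6.10 in the cKO and 85.3 ± 18.9 in the control. Ccn1 (ENSMUSG00000028195.4, listed under its older symbol Cyr61) lies on chromosome 3 from 145646976 to 145649981 on the minus strand in GRCm38, by the GENCODE M21 annotation. The log2 fold change was -2.22 ± 0.38 (SE), with a 95% interval from -3.10 to -1.34, and the edgeR quasi-likelihood p of this single planned test was 0.000415. The exact permutation p was 0.1, the smallest that the design allows, and adjusted over all 11574 genes tested the edgeR p was 0.99999. Which exons were removed was not given in the sources used here, so the residual 21.4% is the level over the whole gene.

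The second comparison asked which other genes differed between cKO and control ependymal cells. The edgeR quasi-likelihood test called 0 of 11574 genes at a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p of 0.05 there were 318 genes, 166 higher and 152 lower in the cKO. Evenly spread p-values would give 579, but this test gave fewer in other splits of the libraries too. The 9 other splits into 3 and 3 gave 257 to 396 genes (median 297), a range that holds the 318. limma-voom also called 0 genes, with 596 at an unadjusted p of 0.05. DESeq2, run without filterByExpr, called 198 of the 12209 genes given an adjusted p, 110 higher and 88 lower in the cKO. The 3 cKO values lay entirely above the 3 control values for 578 genes (4.99%) and entirely below them for 535 (4.62%), where chance gives 10% for both directions together. Library pairs of the same genotype correlated on average at 0.643 and pairs of different genotype at 0.646, across 11574 genes that are not independent replicates (0.804 and 0.808 over the 3480 genes with a mean of at least 50 CPM). Control 1 stood apart on the first principal component, which held 29.2% of the variance, and control 3 on the second, with 21.9%, and edgeR called 0 genes without either one. p-values here measure the spread between these samples, since nothing in the labels says whether they came from separate animals.

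The 24 further named genes were taken by smallest edgeR p, and 0 of them passed the adjustment over all genes by edgeR or limma-voom, while DESeq2 called all 24 over all genes. Jund, which encodes an AP-1 transcription factor subunit, stood at 322 ± 32.9 CPM in the cKO and 729 ± 62.8 CPM in the control, a log2 difference of -1.18 ± 0.16 (SE, adjusted p = 0.779 by the edgeR quasi-likelihood test). Jund lies on chromosome 8 from 70698949 to 70700616. Ifit1, an interferon-induced gene, stood at 132 ± 23.3 against 16.8 ± 7.83 CPM, a log2 difference of 2.98 ± 0.44 (adjusted p = 0.936 by edgeR). Ifit1 lies on chromosome 19 from 34640871 to 34650009 and belongs to a family with near copies between which reads can be shared. Ackr3, an atypical chemokine receptor that takes up CXCL12, stood at 7.62 ± 2.29 against 50.1 ± 14.1 CPM, a log2 difference of -2.71 ± 0.66. Dhrs7, a short-chain dehydrogenase gene, stood at 332 ± 16.7 against 573 ± 45.3 CPM (log2 difference -0.79 ± 0.15). Cyp39a1, an oxysterol 7-alpha-hydroxylase gene, stood at 43.1 ± 19.1 against 143 ± 52.1 CPM (-1.73 ± 0.44), and Coq5, a gene of ubiquinone synthesis, at 47.6 ± 13.2 against 129 ± 21.8 CPM (-1.44 ± 0.33).

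Habp4 stood at 29.9 ± 3.59 CPM in the cKO and 94.0 ± 23.0 CPM in the control, Lypla1 at 45.6 ± 4.22 and 114 ± 24.6 CPM, and Ces1d, a carboxylesterase gene, at 55.1 ± 4.97 and 120 ± 19.3 CPM. Fundc2 stood at 113 ± 32.6 CPM in the cKO and 39.7 ± 1.86 CPM in the control, and Mettl10, a lysine methyltransferase gene, at 199 ± 31.5 and 102 ± 17.2 CPM (SD, n = 3 each). The remaining 13 named genes, Acvr2a aside, were at 3 counts or fewer in all 3 libraries of 1 genotype. Against a floor of 3 counts per library, Ccdc71 was at least 152-fold, Plekha1 at least 148-fold and Map2k6 at least 105-fold higher in the cKO. The cKO 1 library carried the ratios of Plekha1 and Map2k6, which were 43.2-fold and 52.3-fold without it. On the same floor, and with the same limit, Sgk3 was 134-fold, Gopc 126-fold, Slc30a7 88.6-fold and Kcnu1 79.5-fold lower in the cKO. Trim21 had 217, 429 and 465 counts in the cKO libraries and 1, 0 and 0 in the controls, and Wdr3 had 194, 168 and 332 against 1, 0 and 0. Rbpms2 had 468, 98 and 263 counts in the cKO and 1 in each control. Ankib1 and Ubr4 were the reverse, with 0.0985 ± 0.114 and 0.122 ± 0.0424 CPM in the cKO and 24 ± 12.8 and 17.6 ± 10.5 CPM in the control. The activin receptor gene Acvr2a had 1, 15 and 1 counts in the cKO libraries and 649, 398 and 367 in the controls, a log2 difference of -6.21 ± 1.62 (SE) that was -8.61 without cKO 2. In at least 1 library, 70.7% of the 1987 genes with a mean of 100 to 200 counts and 32.8% of the 2038 genes with a mean of 200 to 400 were at 3 counts or fewer. In counts simulated with this spread, the edgeR test recovered 0% of 50 genes changed 2-fold, 12% of those changed 4-fold, 42% at 16-fold and 52% at 64-fold. Among those with a mean of at least 50 CPM it recovered 0 of 14 genes at 2-fold, 6 of 16 at 4-fold, 16 of 17 at 16-fold and 16 of 16 at 64-fold. Over all levels DESeq2 recovered 12%, 34%, 64% and 70% and limma-voom 2%, 10%, 32% and 26%, and of 11374 unchanged genes edgeR called 5, DESeq2 149 and limma-voom 1.

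**Figure D2:**
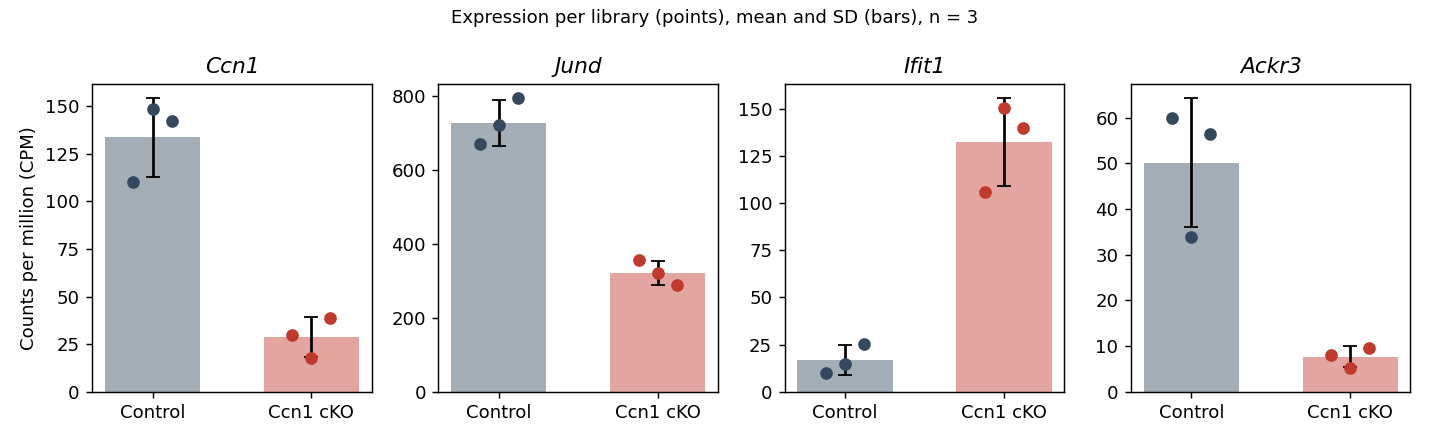
CPM of Ccn1, Jund, Ifit1 and Ackr3 in each library (points), with the mean (bar) and SD (error bar) of the 3 control and the 3 Ccn1 cKO libraries. The genotypes do not overlap for any of the 4 genes, of which Ccn1 was planned and the other 3 were called over all genes by DESeq2 but not by edgeR or limma-voom.

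**Figure D3:**
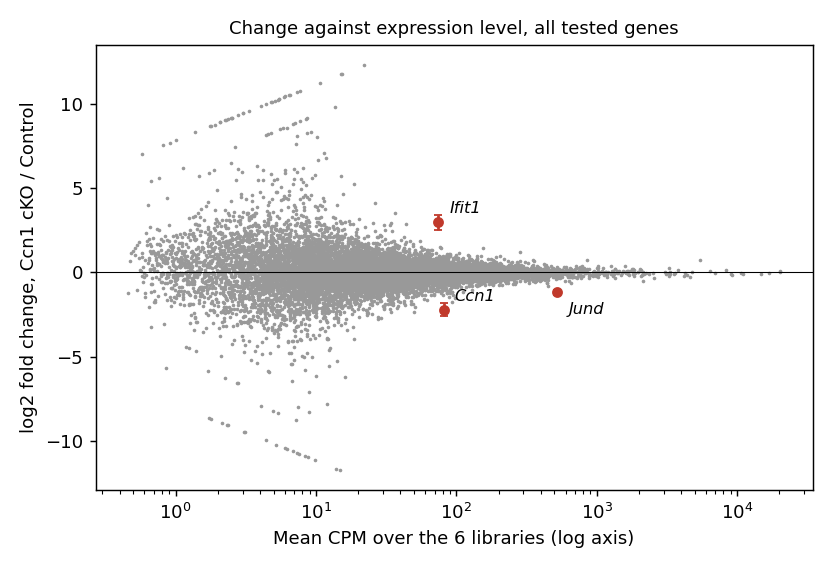
Log2 fold change of the cKO over the control for all 11574 tested genes against their mean CPM over the 6 libraries on a log axis, with Ccn1, Jund and Ifit1 in red with their SE. The lines of points above 7 and below -8 are genes at or near 0 in all 3 libraries of 1 genotype.

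The third comparison asked whether groups of genes moved together. Of 43 fixed lists, 35 had at least 5 tested members, and camera called 0 of them with the preset correlation of 0.01 (4 at an unadjusted p of 0.05, smallest adjusted p = 0.223), 0 with an estimated correlation (smallest adjusted p = 0.823) and fry 0 (smallest adjusted p = 0.176). Within single lists, Ccn1, Jund and Ifit1 were the 3 genes that passed when adjusted over the list alone. Of the 17 tested YAP/TEAD target genes, 9 were higher and 8, Ccn1 included, lower in the cKO. Ccn1 was the only one to pass (adjusted p = 0.00706 adjusted over the list alone, edgeR). Since Ccn1 is the deleted gene, its pass says nothing about the other genes of the list. F3, which encodes tissue factor, stood at 255 ± 46.5 against 358 ± 105 CPM. Of the other CCN family genes only Ccn5 reached a tested level, at 71.3 ± 23.9 against 110 ± 94.3 CPM. Of the 15 tested immediate early genes, 5 were higher and 10 lower, and Jund was the only one to pass (edgeR adjusted p = 0.00101, adjusted over the list alone), while Klf6 stood at 72.5 ± 18.7 against 100 ± 26.1 CPM. Of the 30 tested interferon response genes, 20 were higher and 10 lower in the cKO, with a median log2 difference of 0.33. Ifit1 passed when adjusted over the list alone (edgeR adjusted p = 0.00485), and the list did not (camera adjusted p = 0.356, and adjusted p = 0.982 with an estimated correlation). Taken over all 646 tested genes of the fixed lists, an adjustment chosen after the values were seen, Jund had an edgeR adjusted p of 0.0435, Ifit1 of 0.0523 and Ccn1 of 0.0894.

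The WNT pathway list had the smallest camera p. Of its 15 tested members, 12 were lower and 3 higher in the cKO (median log2 difference -0.70, camera adjusted p = 0.223, and adjusted p = 0.823 with an estimated correlation). Dkk3, a secreted protein of the Dickkopf family, stood at 77.0 ± 17.1 against 131 ± 28.7 CPM, and the transcription factor gene Tcf7l2 at 35.8 ± 3.08 against 78.0 ± 42.0 CPM. Of the 19 tested astrocyte and neural stem cell markers, 16 were lower and 3 higher (median log2 difference -0.19, camera adjusted p = 0.223), with Slc1a2 at 59.9 ± 22.2 against 95.1 ± 19.3 CPM and Gja1, which encodes connexin 43, at 1765 ± 152 against 1847 ± 135 CPM. Nuclear-retained RNAs had a median log2 difference of 0.65 over 6 members (camera adjusted p = 0.223), with Malat1 at 6780 ± 2812 against 4125 ± 574 CPM. The cKO 3 library was the highest for Malat1, whose log2 difference of 0.72 was 0.33 without it. Of the 9 tested NF-kB and inflammatory genes, 6 were higher and 3 lower (camera adjusted p = 0.291). Of the 62 tested motile cilia genes, 29 were higher and 33 lower (median log2 difference -0.029, camera adjusted p = 0.974), with Cfap44 at 87.4 ± 28.9 against 37.1 ± 10.5 CPM and Rfx3, a transcription factor of ciliogenesis, at 22.8 ± 12.2 against 72.6 ± 23.3 CPM.

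Among genes of signalling to the neighbouring niche edgeR called 0 over all genes, and of those printed here DESeq2 called Adam17 (adjusted p = 0.0349) and Sparc (adjusted p = 0.0132). By edgeR neither passed over its list alone (adjusted p = 0.471 and 0.306). In the 9 other splits of the libraries into 3 and 3, DESeq2 called 150 to 260 genes, so its calls need caution. Of the 10 tested EGF family ligands, receptors and sheddases, 5 were higher and 5 lower, and the sheddase gene Adam17 stood at 11.9 ± 2.73 against 37.3 ± 11.3 CPM. Of the 22 tested BMP and TGF-beta pathway genes, 7 were higher and 15 lower (camera adjusted p = 0.623), with Tgfbr2 at 44.8 ± 4.5 against 5.79 ± 4.54 CPM. Of the 14 tested Notch pathway genes, 10 were higher and 4 lower (camera adjusted p = 0.974), with Dner at 2.28 ± 3.57 against 34.9 ± 11.6 CPM and Hey1 at 144 ± 29.4 against 183 ± 37.5 CPM. Dner had 0, 86 and 6 counts in the cKO libraries. Its log2 difference was -7.25 without cKO 2 and -3.35 without cKO 1. Of the 18 tested growth factors and cytokines, 8 were higher and 10 lower (camera adjusted p = 0.548), with Cntf at 50.8 ± 8.37 against 95.8 ± 18.9 CPM and the midkine gene Mdk at 239 ± 27.3 against 200 ± 22.0 CPM. Of the 15 tested extracellular matrix genes, 8 were higher and 7 lower, and Sparc stood at 2290 ± 44.4 against 2826 ± 217 CPM. Of the 20 tested cell cycle genes, 12 were higher and 8 lower (camera adjusted p = 0.974), with Cenpf at 18.9 ± 11.6 against 1.27 ± 1.82 CPM and Pcna at 68.7 ± 31.1 against 90.8 ± 35.4 CPM. Cenpf had 0, 46 and 7 counts in the controls. Its log2 difference was 3.31 without control 1 and 6.35 without control 2.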

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

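Ccn1 was lower in the cKO at an unadjusted p under 0.05 in 10 of 10 alternatives (log2 -2.27 to -2.21) and in 6 of 6 fits without 1 library (-2.50 to -1.97). Its p adjusted over all genes ran from 4.17e-06 with DESeq2 to 0.99998. Of 12 settings chosen beforehand for the count of genes, 11 called 0. DESeq2 called 198 (110 higher and 88 lower in the cKO). Each fit without 1 library called 0 genes and 0 lists, and all 8 settings chosen beforehand for lists called 0. In total 13 further settings for genes were tried after the data had been seen, and 8 of them called 0. The cutoff of 50 CPM was chosen after Jund and Ifit1 were seen to have the smallest p, so its calls of these genes are not independent evidence. A mean of at least 50 CPM called 2 genes (1 higher, Ifit1, and 1 lower, Jund, both at adjusted p = 0.0466) and 1 list, interferon response (adjusted p = 0.954 with an estimated correlation). A mean of at least 20 CPM called 0 genes and 2 lists, WNT lower and interferon response higher (adjusted p = 0.915 and 0.934 with an estimated correlation), and a mean of at least 10 CPM called none of either. Means of at least 100 and 200 CPM called 1 gene each, Jund (1 lower), and 0 lists. The newer quasi-likelihood method called 0 genes after the main filter and 2 (Ifit1 and Jund, 1 higher and 1 lower) with all genes or with a mean of at least 50 CPM. The other 5 settings called 0, and the cause was not tested. Among genes with a mean of at least 50 CPM, leaving out 1 library ended both gene calls in 5 of 6 fits. Jund passed without control 1 (adjusted p = 0.0499), and the adjusted p of Jund reached 0.829 without cKO 2. The interferon list call there ended without cKO 2, control 1 or control 2 (adjusted p = 0.601, 0.272 and 0.0844), and the WNT list was called as well without cKO 1. Ccn5 changed sign to 0.18 with limma-voom and to 0.089, 0.12 and 0.089 on log2(TPM + 1), log2(TPM + 0.1) and unfiltered TPM, and the cause was not tested. Leaving out 1 library turned Acta2 (-0.13 to 0.31), Ccn5 (-1.17 to 0.11), Hbegf (-0.84 to 0.068), Itgb5 (-1.39 to 0.050), Itm2a (-0.23 to 0.42) and Spred1 (-1.09 to 0.26). With the replicate number as a block, 0 genes and 0 lists were called and Ccn1 stood at -2.27. Same-numbered samples deviated together at correlations of 0.0080, 0.031 and 0.015, too little to pair them, although 6 of 6 samples correlated best with their own number, a hint from the data and not from the design.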

Other observations

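The tests on splits of the samples for DESeq2, all gene counts and lists, of missed transcripts and simulated counts, of GC content, of single-exon genes in the form given, and on the Ifit genes and the interferon list were chosen after the result was seen, while the splits among genes with a mean of at least 50 CPM were set before theirs.

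Of the sex-linked genes, Tsix had 170, 82 and 25 counts in the cKO libraries and 119, 118 and 258 in the controls, and Xist, to which it is antisense, had 0, 0 and 204 against 1, 19 and 11. Whether counting used the strand is not given in the sources used here, so reads of this pair cannot be assigned with certainty. Gapdh, a glycolytic enzyme gene often used as a reference, stood at 523 ± 92.6 against 797 ± 109 CPM with no overlap of the groups, and Kcnj10, an inwardly rectifying potassium channel gene, at 113 ± 11.6 against 62.1 ± 5.48 CPM. Neither passed over its list alone by edgeR (adjusted p = 0.263 and 0.234), while DESeq2 called Kcnj10 over all genes (adjusted p = 0.0039).

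DESeq2 called 198 genes where edgeR and limma-voom called 0. In 61.6% of these calls all 3 libraries of 1 genotype were at 3 counts or fewer, and in simulated counts with the same spread DESeq2 also called 149 of 11374 unchanged genes (edgeR 5), while it recovered more of the changed ones than edgeR. The 9 other splits of the libraries gave 48.7% to 67.5%, so the 61.6% is not particular to the split by genotype. Calls that come from transcripts missed in single libraries, with a spread set too low for them, could give both the 61.6% and the 149. With 10 splits of the 6 samples no share under 0.05 can be reached: 4 of the 10 gave as many DESeq2 calls (198 in the real split, at most 260 in the others). A biological difference between the genotypes in part of the 198 genes stays open.

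Splits of the 6 samples into 3 and 3 are 10, too few for a share under 0.05, and 5 of the 10 gave at least as many genes at an unadjusted p of 0.05 by edgeR (318 real, highest other 396). For genes and lists past the adjusted threshold the real value was 0, which all 10 splits must reach, so the comparison says nothing there (highest other 0 genes and 3 lists).

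Jund was lower in the cKO in all 3 libraries, and it has 1 exon and a GC content of 67.1% by GENCODE M21. The 31 other nuclear single-exon protein-coding genes with a mean of at least 50 CPM had a median log2 difference of 0.061 ± 0.094 (SE), mitochondrially encoded genes left out, which argues against DNA or nuclear RNA read as intronless genes. Genes within 3 points of its GC content, only 6, had a median of -0.020, and the 112 genes within 8 points, a window widened because of that, -0.043 ± 0.032, which argues against a GC bias. Among genes with a mean of at least 50 CPM, a cutoff chosen after Jund and Ifit1 were seen to have the smallest p, 1 of the 10 splits gave as many calls (2 real, highest other 0), too few splits for a share under 0.05. The cause of the lower level stays open.

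Ifit1 was higher in all 3 cKO libraries, by 116 CPM, and reads moved from near copies would need the other 5 Ifit genes to be lower by as much. Their sum was 69.6 ± 66.5 CPM (SE) higher (exact permutation p = 0.3), with only Ifit2 (-29.2 CPM) and Ifit1bl1 (-3.31 CPM) lower, but the sum of all 6, 185 ± 79.9 CPM higher, overlapped between genotypes (exact permutation p = 0.2), so this stays open. A wider interferon response also stays open, since the other 29 interferon response genes had a median log2 difference of 0.32, with a camera p of 0.536 at an estimated correlation. The list passed with a preset correlation among genes with a mean of at least 50 CPM (13 genes), but its p there was 0.186 with an estimated correlation. In that filter 6 of the 10 splits called as many lists (1 real, highest other 4), too few splits for a share under 0.05.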
